A study of Oryza sativa with 14 samples.

How the data were processed

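Transcript levels were measured with the Affymetrix GeneChip Rice Genome Array in 14 RNA pools from 7 groups of rice (Oryza sativa ssp. japonica), 2 pools per group. Each pool came from 6 whole seedlings, per the labels, 12 days old after 2 days in the dark and 10 days under a 12 h photoperiod at 28 °C. The groups were 4 modified lines and 3 unmodified controls, 1 control per cultivar. Both transgenic lines germinated on medium with 30 mg/L hygromycin B, per the labels, and the controls and mutants did not, so the antibiotic and the transgene cannot be separated in these comparisons.

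The deposited values are log2 expression, made by the authors with Robust Multichip Average in Partek Genomics Suite, per the labels' design text. That procedure corrected the perfect-match probes for background, brought all arrays to a common distribution, took log2 and summarised each probe set by median polish. Versions of these programs are not given in the sources used here. The values carry 2 decimals, and the array medians lay between 5.83 and 5.89. Replicate 1 is the array whose title bears a number and replicate 2 the one whose title bears none. All 14 columns were used, as deposited, with no further normalization.

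The table holds 57381 probe sets, of which 187 control probe sets were left out of the tests. The 64 reporter probe sets among these were tested separately. Gene names came from a reference gene table (assembly ASM3414082v1) through the transcript identifiers in the array annotation, and no coordinates of that assembly are printed. One gene was found for 22436 of the 57194 tested probe sets, several genes for 95 and no gene for 34663. The 17905 genes found were each represented by the probe set with the highest mean over all arrays, and 2442 of them had an informative symbol or synonym. A gene with no such name is given by its LOC identifier.

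Differences were tested with limma 3.58.1 in R 4.3.3. One mean per group was fitted over all 14 arrays, which left 7 residual degrees of freedom, and eBayes with default settings added a prior of 4.57 degrees of freedom. Each modified line was compared with the control of its own cultivar, the unstable lines with each other, and the 3 controls by a moderated F-test. Differences between line effects were tested as interaction contrasts. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The number of arrays limits the precision, and all p-values measure the spread between these pools, not between independently made lines. As a size that depends on no threshold, the standard deviation of the true log2 differences was estimated as the square root of the covariance between differences from disjoint arrays. The mean of both pairings of the arrays was taken.

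Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 29 lists per comparison. Of the 32 lists written, 3 had fewer than 5 members on the array and were not tested. The lists cover genome maintenance, stress and defence, hormones, cell walls, nutrition, translation and markers of shoot, root and grain. The comparisons, tests, alternatives, lists and naming rule were fixed before the data were examined. The reference table held no gene descriptions, so the lists' description patterns were rewritten as symbol and synonym patterns. That was done after the array correlations and the reporter values had been seen, and before any comparison of genes.

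The naming rule took, for each line, up to 10 named genes with the largest rise and 10 with the largest fall. These had to be called, with both arrays of the line beyond both control arrays and a higher-group mean at or above the median of 5.86. It also took up to 4 called members per list, or the 2 largest changes of a list with none. The comparison of the unstable lines and that of the controls took 5 each way. The dwarf genes in the stable mutant were always taken. Genes known by a LOC identifier alone, and probe sets with no gene, fall outside this rule and were chosen after their values were seen.

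Overlaps of calls were set against the product of the list sizes over the probe sets tested. For the lines that share the Nipponbare control, 20 simulations of unchanged groups against these controls were added. The alternatives were other variance moderation, each comparison's own arrays alone, a filter on dim probe sets, removal of probe sets shared between transcripts, cyclic loess, a fold threshold of 2, a replicate block and each array left out in turn. A lone array in such a fit is assumed to vary like the other groups. The probe sets not called among the cultivars, and separate control arrays for the unstable lines, were added as alternatives after the data had been seen. Signal over background was not tested, since detection calls were not analysed here.

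The limma step was tested on simulated data with 57194 probe sets, 200 of them changed. It recovered 94% of 2-fold and 28.4% of 1.5-fold changes in the simulated stable transgenic comparison, with 3.27% false calls. In the simulated stable mutant comparison these shares were 92.5%, 32.8% and 4.46%. They were 89.6%, 23.9% and 5.96% for the simulated unstable transgenic line, and 91% (2-fold), 28.4% (1.5-fold) and 2.03% (false) for the simulated unstable mutant. The simulated noise was independent and of equal size in all groups by construction. These shares are therefore not error rates of the real calls, where the spread may differ between groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.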

Results

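Whole-seedling transcript levels were compared between modified rice lines and unmodified plants of the same cultivar, to ask whether mutagenesis or transgene insertion goes with more transcript changes. The stable transgenic line (cv. Bengal, T3 generation) expresses a single-chain antibody against carcinoembryonic antigen. The stable mutant (cv. Estrela A) descends from gamma-irradiated seed through more than 10 selfing generations and grows about 45 cm shorter. The unstable transgenic line (cv. Nipponbare, T1) carries 1 copy of the BCBF1 gene under the stress-inducible Arabidopsis RD29A promoter and 1 copy of hpt II, which confers hygromycin resistance. The unstable mutant (cv. Nipponbare, M1) received 100 Gy. Each group had 2 arrays, and values are log2 means ± SD (n = 2) unless stated otherwise. Replicate arrays correlated across probe sets with r between 0.993 and 0.997, where probe sets are not independent replicates. Signal over background was not tested, so a fold against a low level depends on the background of the array.

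The arrays of the stable lines lay beside their own controls, with r of 0.994 to 0.995 for the stable transgenic line and 0.994 to 0.996 for the stable mutant. The unstable transgenic arrays correlated with the Nipponbare control at 0.981 to 0.990. The unstable mutant arrays reached 0.971 to 0.978 with the Nipponbare control and 0.972 to 0.974 with the Bengal control, a different cultivar. They stood apart on the third principal component, at scores of -86.1 and -80.5.

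**Figure D1:**
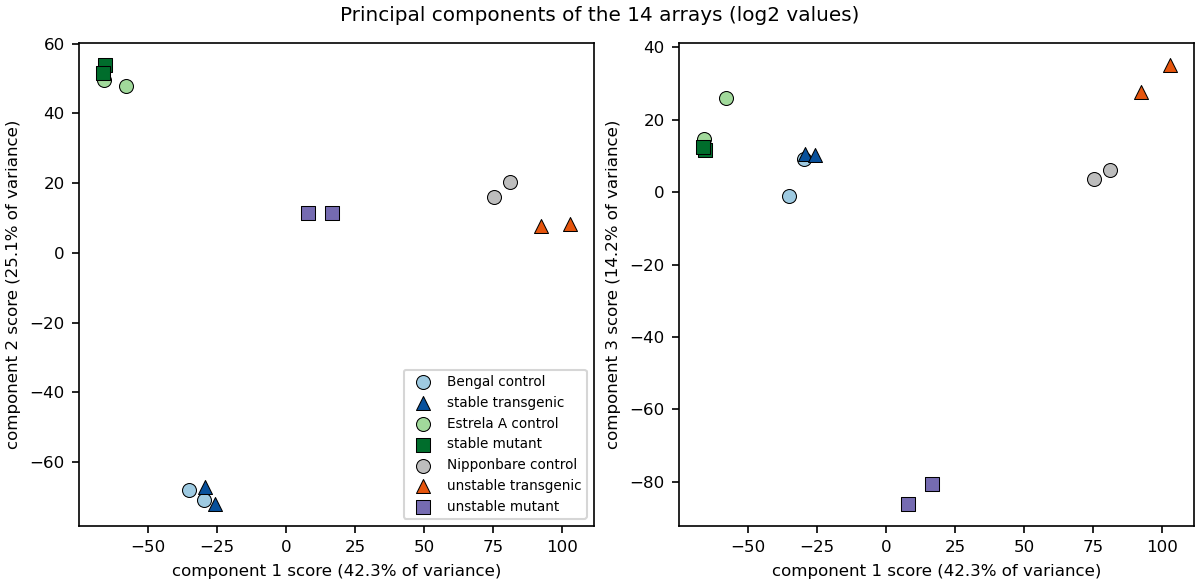
Scores of the 14 arrays on principal components 1 and 2 (left) and 1 and 3 (right) of the log2 values, with 2 points per group. The stable lines overlie their controls, and the unstable mutant lies alone at component 3 scores of -86.1 and -80.5.

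One of the 64 reporter probe sets, known here by a sequence identifier alone, set the stable transgenic line apart. It read 13.18 ± 0.05 in the stable transgenic line and 4.68 ± 1.00 in the Bengal control, a log2 difference of 8.50 (SE 0.32, limma adjusted p = 6.1e-10 over the reporters). It read 4.99 ± 0.04 in the unstable transgenic line and 3.83 ± 0.24 in the Nipponbare control, a log2 difference of 1.16 (SE 0.32) that did not pass (adjusted p = 0.237 over the reporters). The other 63 lay between 2.90 and 7.34 on every array. None passed in the other line comparisons with limma, where 2 (stable mutant), 9 (unstable transgenic) and 9 (unstable mutant) had an unadjusted p under 0.05. What that identifier stands for was not traced here, so it stays open whether this reporter is a selection marker. Its low level in the unstable transgenic line, whose label gives it hpt II, therefore leaves that label open. Bengal control replicate 2 read 5.39, above both arrays of that line (4.96 and 5.01). The labels say that the line germinated on hygromycin B.

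In the stable transgenic line, few named genes differed from Bengal, all by less than 2-fold. The peroxiredoxin gene PRXIIE-2 (LOC4328586) rose 1.87-fold, from 8.97 ± 0.13 to 9.87 ± 0.02 (SE of the log2 difference 0.10, adjusted p = 0.00371). LFNR1, a leaf ferredoxin-NADP reductase, rose 1.77-fold (adjusted p = 0.0133) and IPP (LOC4330457) 1.51-fold (adjusted p = 0.0340). CAB2R (LOC4324599), a chlorophyll a/b binding protein gene, was 1.58-fold lower (adjusted p = 0.0170), and Melibiase (LOC4348988) was 1.60-fold lower (adjusted p = 0.0362). None of these 5 genes passed when only the Bengal arrays were fitted. Of the 4 fits that left out 1 array, PRXIIE-2 lost its call in 2 (highest adjusted p = 0.0504, without stable transgenic replicate 1) and LFNR1 in 3 (0.149, without Bengal control replicate 1). CAB2R lost it in 3 and Melibiase in 4 (0.152 and 0.225, both highest without stable transgenic replicate 1), and IPP in 4 (0.285, without Bengal control replicate 1). Larger changes were seen in genes known by an identifier alone, chosen after their values were seen. LOC4331576 rose 7.84-fold (6.97 ± 0.07 against 4.0 ± 0.23, adjusted p = 6.09e-06) and LOC4335593 was 7.31-fold lower (5.06 ± 0.38 against 7.93 ± 0.28, adjusted p = 0.000123). A probe set with no gene name rose by 5.50 on the log2 scale from a low level (9.40 ± 0.08 against 3.91 ± 0.08).

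As groups, the photosynthetic apparatus and jasmonate lists shifted upward by small amounts in the stable transgenic line. Of 29 photosynthesis genes, LFNR1 rose, CAB2R fell and 27 did not pass, with a median log2 difference of 0.16 (camera adjusted p = 0.000633). The call was lost with an estimated correlation (adjusted p = 0.781 with an estimated correlation), while adjusted over the list alone 6 genes rose and 1 fell. None of 35 jasmonate genes passed in limma over all genes or adjusted over the list alone, at a median of 0.15 (adjusted p = 0.0293, and adjusted p = 0.992 with an estimated correlation). Without stable transgenic replicate 1 the adjusted p was 0.968 for the jasmonate list, with its direction turned, and 0.0995 for photosynthesis. Without Bengal control replicate 1 it was 0.311 for the jasmonate list. PRXIIE-2 was the sole called member of the 49 antioxidant genes. Root markers (0 of 13 called, median -0.19) and grain remnant markers (0 of 15, median -0.13) did not pass by camera (adjusted p = 0.319 and 0.0893).

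Over all probe sets, 94 of 57194 were called in the stable transgenic line, 74 higher and 20 lower, and 4145 had an unadjusted p under 0.05. Of these, 59 changed at least 2-fold, and the effect SD was 0.104. The count was 24 without variance moderation, 28 from the Bengal arrays alone, 152 with a trended robust prior, 51 without stable transgenic replicate 1 and 60 without either Bengal control array.

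In the stable mutant, XB3 (LOC4337598), a ubiquitin ligase known as a partner of the resistance kinase XA21, rose 3.71-fold, from 4.92 ± 0.30 to 6.81 ± 0.02 (SE 0.13, adjusted p = 3.46e-05). The homeobox gene WOX6 (LOC4332705) was 2.66-fold lower (4.74 ± 0.23 against 6.15 ± 0.19, adjusted p = 0.00306). GH3.2 (LOC4326893), an enzyme that conjugates auxin to amino acids, was 2.55-fold lower (adjusted p = 0.0167). WOX6 lost its call in the Estrela A arrays alone, without stable mutant replicate 2 (adjusted p = 0.0627) and without Estrela A control replicate 2. GH3.2 lost it whichever of the 4 arrays was left out (at most 0.188, without stable mutant replicate 2). The largest rise, chosen after its value was seen, was LOC4346960, by 8.18 on the log2 scale from a low level of 3.58 ± 0.13 to 11.76 ± 0.10 (adjusted p = 1.75e-10). LOC4346944, near it in gene order, rose by 4.58 on the log2 scale, to 8.18, while the Nipponbare control stood at 7.18. LOC4343322 rose by 4.91 to 9.84, with the Nipponbare control at 8.68. A probe set with no gene name fell by 6.20 on the log2 scale, from 10.23 ± 0.01 to 4.03 ± 0.21.

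None of the 30 genes of gibberellin, brassinosteroid and strigolactone pathways, in which many rice dwarf mutations lie, passed in limma in this short line, over all genes or adjusted over the list alone. Their differences ran from -0.35 (CYP714D1) to 0.25 (SLRL1).

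In the stable mutant 5 lists leaned downward and 1 upward by camera at the preset correlation, with few or no members called, and each of the 6 calls was lost (adjusted p = 0.594 with an estimated correlation). None of the 26 ribosomal protein genes was called (median -0.16, adjusted p = 6.53e-06, and adjusted p = 0.594 with an estimated correlation), with RPS26 at a log2 difference of -0.35 and RPL39C at -0.32. The 29 DNA repair genes (median -0.13, adjusted p = 0.000169), 49 cell cycle genes (median -0.18, adjusted p = 0.00155) and 30 translation and chaperone genes (median -0.13, adjusted p = 0.00155) likewise had 0 members called, and all 3 lists had an adjusted p = 0.594 with an estimated correlation. Adjusted over the list alone, 2 DNA repair genes were lower. Of 60 auxin genes, GH3.2 fell and 59 did not pass (adjusted p = 0.0312, and adjusted p = 0.594 with an estimated correlation), and 3 fell adjusted over the list alone. The 51 heat shock genes leaned upward with none called (median 0.07, adjusted p = 0.0121, and adjusted p = 0.594 with an estimated correlation). The cell cycle call was also lost without Estrela A control replicate 2 (adjusted p = 0.462), the heat shock call without stable mutant replicate 1 (0.0874) and the auxin call without either of these arrays (0.0872 and 0.0874). Root markers (median 0.00, adjusted p = 0.815) and photosynthesis genes (median 0.02, adjusted p = 0.0841) did not pass.

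In total, 75 probe sets were called in the stable mutant, 39 higher and 36 lower, 53 of them by at least 2-fold, against 3797 with an unadjusted p under 0.05. The effect SD was 0.134. The count fell to 47 without stable mutant replicate 2, and 49.4% of the calls were higher after cyclic loess, against 52%.

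In the unstable transgenic line, genes of jasmonate signalling and of the DREB1 cold and drought regulators rose far above the Nipponbare control. JAZ13 (LOC4348531), 1 of the JAZ repressors that jasmonate itself induces, rose 41.4-fold, from 5.19 ± 0.38 to 10.56 ± 1.71 (SE 0.58, adjusted p = 0.000406). DREB1G (LOC4330306) rose 32.7-fold (9.50 ± 1.39 against 4.47 ± 0.47, adjusted p = 0.000145) and DREB1B (LOC4347618) 11-fold (9.66 ± 1.92 against 6.20 ± 0.10, adjusted p = 0.00866). TPP1 (LOC4330221), a trehalose-6-phosphate phosphatase, rose 12.1-fold (11.45 ± 1.36 against 7.86 ± 0.02). EP3A, CPK21, LIS and BC1L9 rose by 14.6-, 7.86-, 7.16- and 6.75-fold. Among the falls, SPX2 (LOC4328654), of the phosphate-sensing SPX family, was 5.92-fold lower (adjusted p = 0.000143) and the high-affinity nitrate transporter NRT2.3 (LOC4324249) 2.51-fold lower. The peroxidase gene LOC4344277 was 4.96-fold lower and CIPK5 3.56-fold lower. Of these 12 genes, only EP3A and the peroxidase gene kept their calls when the 4 arrays of the comparison were fitted alone. Without replicate 1 of the line the folds of JAZ13, DREB1G, DREB1B, TPP1 and LIS were 17.9, 16.6, 4.29, 6.21 and 4.61, and without replicate 2 they were 95.7, 64.5, 28.3, 23.5 and 11.1.

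**Figure D2:**
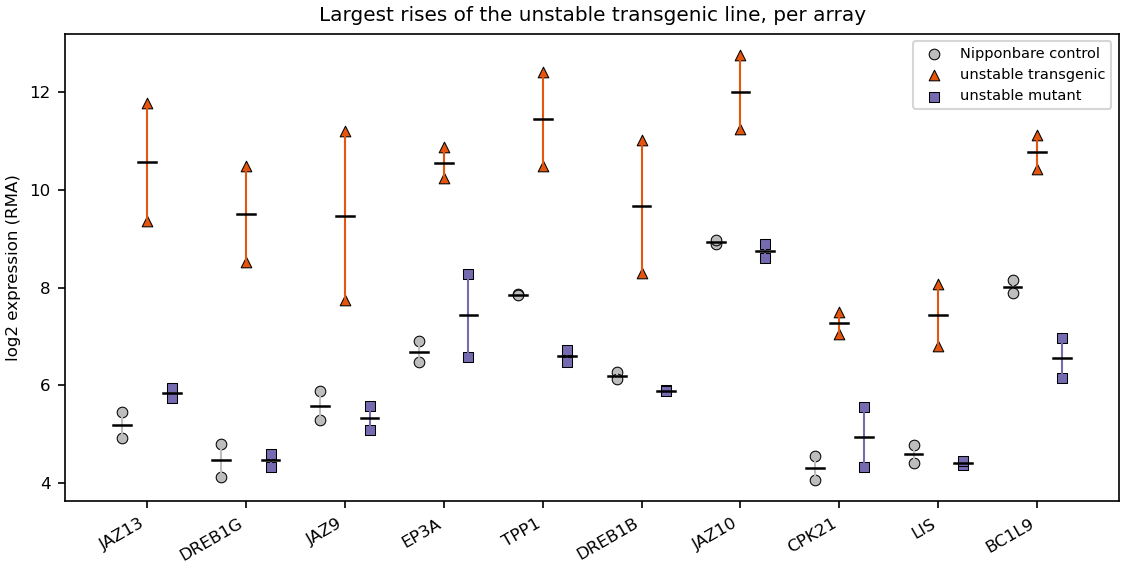
Log2 expression per array of the 10 named genes with the largest rise in the unstable transgenic line, for the Nipponbare control, that line and the unstable mutant (2 points per group, black bar at the mean). The transgenic arrays lie above both control arrays for every gene, and JAZ9 spans 7.74 to 11.19 between them.

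Of 35 jasmonate genes in the unstable transgenic line, 17 rose and 18 did not pass (median 0.68, camera adjusted p = 1.76e-07, and adjusted p = 0.517 with an estimated correlation). Adjusted over the list alone, 20 rose and 2 fell. JAZ9 rose 14.7-fold, JAZ10 8.34-fold and OPR1, an oxophytodienoate reductase, 5.62-fold. JAZ9 and JAZ10 stood above every other group. For OPR1 the Nipponbare control was the lowest group, at 7.33. The line read 9.82 for OPR1, against 9.27 in Bengal, 8.475 in Estrela A and 10.16 in the stable transgenic line. All 17 called jasmonate genes stood higher on replicate 1 of the line than on replicate 2, by a median of 0.78. Of 10 AP2/ERF and DREB genes, 5 rose (median 0.79, adjusted p = 0.00452, and adjusted p = 0.420 with an estimated correlation), and 7 adjusted over the list alone. All 5 stood higher on replicate 1 of the line than on replicate 2, by a median of 1.65. CBF3 (LOC4347620) rose 3.75-fold and DREB1E 3.24-fold. Of 23 cold, drought and abscisic acid genes, 8 rose (median 0.43, adjusted p = 0.0220, and adjusted p = 0.517 with an estimated correlation), and 9 adjusted over the list alone. LEA19 rose 6.54-fold and the dehydrin genes RAB16B and RAB21 6.26- and 3.92-fold. For these genes the Nipponbare control was the lowest of the 7 groups, and the line stayed below all remaining groups. LEA19 read 7.86 in that control and 10.57 in the line, against 12.82 in Bengal and 11.91 in Estrela A. RAB16B read 5.4 and 8.045, against 11.08 and 9.205, and RAB21 8.68 and 10.65, against 13.54 and 12.89. By contrast DREB1E, at 6.655 in the line, stood above every other group. Without Nipponbare control replicate 1, CBF3 (adjusted p = 0.106), DREB1E (0.0837), RAB16B (0.0619) and RAB21 (0.112) lost their calls, and OPR1 did without unstable transgenic replicate 1 (0.0754). The folds of JAZ9, JAZ10, CBF3 and DREB1E were 4.44, 4.93, 2.11 and 1.84 without replicate 1 of the line and 48.5, 14.1, 6.64 and 5.70 without replicate 2. Those of LEA19 and RAB21 were 3.48 and 2.38 without Nipponbare control replicate 1 and 12.3 and 6.45 without its replicate 2.

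Defence genes rose in the same arrays of the unstable transgenic line, with 7 of 25 called (median 0.38, adjusted p = 0.00267, and adjusted p = 0.420 with an estimated correlation) and 14 higher and 1 lower adjusted over the list alone. The chitinase genes Cht4 and Cht1 rose 3.25- and 3.23-fold (Cht1 at an adjusted p of 0.0658 without Nipponbare control replicate 1). Cht1 read 4.57 in the Nipponbare control and 6.26 in the line, against 7.24 in Bengal and 8.17 in Estrela A. For Cht4 these levels were 9.585, 11.29, 11.43 and 11.75. Of 81 cell wall genes 15 rose and 1 fell (adjusted p = 0.0117, and adjusted p = 0.517 with an estimated correlation), against 18 and 1 adjusted over the list alone. BC1L6, of the COBRA-like family, rose 3.51-fold and the endoglucanase gene GLU11 2.39-fold. Of 49 cell cycle genes 5 rose (adjusted p = 0.0220, and adjusted p = 0.663 with an estimated correlation), and 7 adjusted over the list alone. These included the D-type cyclins CYCD5-3 (2.19-fold) and CYCD4-2 (1.71-fold). Photosynthesis genes fell in 5 of 29 (median -0.09, adjusted p = 0.00267, and adjusted p = 0.559 with an estimated correlation), with 1 higher and 7 lower adjusted over the list alone. PORB was 1.40-fold lower and the chloroplast regulator GLK1 1.40-fold lower, and both lost the call without unstable transgenic replicate 1 (adjusted p = 0.149 and 0.130). Root markers leaned downward beside these groups (median -0.37, adjusted p = 0.0122, and adjusted p = 0.420 with an estimated correlation), although of 13 members NRT2.3 fell and NAR2.2 rose (NAR2.2 at 0.280 without Nipponbare control replicate 1). Adjusted over the list alone 1 rose and 3 fell. The call for cell cycle genes was lost without Nipponbare control replicate 1 (adjusted p = 0.129) or unstable transgenic replicate 2 (0.190), that for cell wall genes without the latter (0.0634) and that for cold and drought genes without unstable transgenic replicate 1 (0.0893).

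Other groups moved in part in the unstable transgenic line without a call by camera. Among 51 heat shock genes 5 rose, with the heat shock factor HSFA3 6.11-fold higher, and 4 fell. WRKY76 and wrky38 rose 4.39- and 5.13-fold among 6 WRKY genes, WRKY76 at an adjusted p of 0.114 without unstable transgenic replicate 1. Of 60 auxin genes 12 rose and 2 fell, and of 32 phenylpropanoid genes 6 rose, 4CL5 by 4.45-fold (adjusted p = 0.0988 without the same array), and 1 fell. Cytochrome P450 genes rose in 6 of 29 (CYP74A1, an allene oxide synthase gene, 3.66-fold), and antioxidant genes rose in 5 and fell in 2 of 49. Nitrate and phosphate genes rose in 3 and fell in 5 of 29, with the phosphate transporter gene PHT1-8 2.60-fold higher. The folds of HSFA3, WRKY76, wrky38 and 4CL5 were 3.904, 2.69, 2.87 and 2.85 without unstable transgenic replicate 1 and 9.55, 7.19, 9.19 and 6.96 without replicate 2. None of the 26 ribosomal protein genes was called.

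Altogether 4425 probe sets (7.74%) were called in the unstable transgenic line, 2652 higher and 1773 lower, and 1020 changed at least 2-fold. The effect SD was 0.310. The call count depended strongly on the pooled variance, with 35 from the 4 Nipponbare arrays of the comparison alone (9619 at an unadjusted p under 0.05) and 2318 without moderation. It was 1349 without unstable transgenic replicate 1, 1741 without Nipponbare control replicate 1 and 1522 among probe sets not called between cultivars, an alternative added after the data had been seen.

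In the unstable mutant, the named genes with the largest changes included late embryogenesis and dehydrin genes that rose and transporter genes that fell. BURP16 (LOC4348595) rose 49.5-fold, from 8.15 ± 0.42 to 13.78 ± 0.04 (SE 0.37, adjusted p = 1.65e-06). LEA19 rose 21.9-fold (12.31 ± 0.00 against 7.86 ± 1.29) and the dehydrin gene RAB21 (LOC4350454) 14.2-fold (12.51 ± 0.07 against 8.68 ± 1.02). APG8D, ELA3 and the copper transporter gene COPT2 rose 16.8-, 15.8- and 11-fold. The folds of LEA19, RAB21 and ELA3 were 11.6, 8.63 and 8.79 without Nipponbare control replicate 1 and 41.1, 23.4 and 28.5 without its replicate 2. JAZ2 (LOC4342421) fell by 7.30 on the log2 scale, to a low level (3.31 ± 0.13 against 10.61 ± 0.01, adjusted p = 5.21e-12). The root iron transporter gene IRT1 (LOC4333669) was 37.4-fold lower (5.84 ± 0.04 against 11.07 ± 0.26), and the nitrate transporter genes NRT2.2 and NRT2.3 were 24.3- and 13.9-fold lower. Several of these levels matched the other cultivars. JAZ2 read 3.36 in Bengal and 3.50 in Estrela A, IRT1 read 5.57 and 5.53, and BURP16 read 13.61 and 13.30. LEA19 read 12.82 and 11.91 in these cultivars. APG8D read 8.985 in the mutant, against 8.955 and 9.195. NRT2.2 read 5.01, against 4.87 and 5.085, and NRT2.3 read 5.44, against 5.41 and 5.125. For these genes the Nipponbare control stood apart from the mutant and from both other controls. COPT2, at 9.89 in the mutant, stood above both (8.66 and 9.12). OsC3H40, by contrast, read 10.41 in the mutant and 9.96 in Nipponbare, against 4.42 in Bengal.

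The water deficit, nitrate and phosphate, and iron lists were not called in the unstable mutant. Of 23 cold, drought and abscisic acid genes 7 rose and 2 fell (camera adjusted p = 0.232), or 8 and 4 adjusted over the list alone. Of 29 nitrate and phosphate genes 4 rose and 8 fell (adjusted p = 0.352), or 5 and 10 adjusted over the list alone. Of 31 iron acquisition genes 4 rose and 5 fell (adjusted p = 0.897), or 5 and 5 adjusted over the list alone.

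Root markers fell in 10 of 13 genes in the unstable mutant (median -1.38, camera adjusted p = 9.9e-06, and adjusted p = 0.142 with an estimated correlation), and in 11 adjusted over the list alone. The ammonium transporter gene AMT1-2 was 4.18-fold lower. It read 6.87 in the mutant, near Bengal (6.57) and Estrela A (6.605), while the Nipponbare control read 8.935. Beside the root markers, 40 of 81 cell wall genes fell and 5 rose (median -0.38, adjusted p = 9.9e-06, and adjusted p = 0.273 with an estimated correlation), against 46 and 6 adjusted over the list alone. The endoglucanase gene GLU15 was 13.9-fold lower and the expansin gene EXPA3 6.99-fold lower. GLU15 read 4.5 in the mutant, near Bengal (4.58) and Estrela A (4.465), while EXPA3, at 5.47, lay below both (6.535 and 6.57). Phenylpropanoid genes fell in 15 of 32 and rose in 3 (adjusted p = 0.0286, and adjusted p = 0.338 with an estimated correlation), or 16 and 4 adjusted over the list alone, with 4CL1 3.56-fold lower. Diterpenoid phytoalexin genes fell in 9 of 16 (median -1.49, adjusted p = 0.00853, and adjusted p = 0.837 with an estimated correlation), and in 10 adjusted over the list alone. CYP701A8 was 30.2-fold lower and the copalyl diphosphate synthase gene CPS2 26.9-fold lower. CPS2 read 4.005 in the mutant, near Bengal (3.89) and Estrela A (4.305), while CYP701A8, at 4.395, lay below both (7.135 and 5.54). The control arrays themselves differed in the diterpenoid genes. All 9 were higher on Nipponbare control replicate 1, by a median of 2.50, and without that array the adjusted p was 0.106 and the folds of CYP701A8 and CPS2 were 10.97 and 8.43. Without Nipponbare control replicate 2 these folds were 83.0 and 85.9.

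Ribosomal protein genes fell in 13 of 26 in the unstable mutant (median -0.34, camera adjusted p = 0.000502, and adjusted p = 0.837 with an estimated correlation), with RPS26 1.74-fold lower, and adjusted over the list alone 17 fell and 1 rose. Cell cycle genes fell in 21 of 49 and rose in 7 (adjusted p = 0.0274, and adjusted p = 0.837 with an estimated correlation), with 23 and 7 adjusted over the list alone. The replication helicase genes MCM5 and MCM4 were 2.67- and 2.57-fold lower. Translation and chaperone genes fell in 10 of 30 and rose in 1 (adjusted p = 0.0323, and adjusted p = 0.837 with an estimated correlation), or 12 and 3 adjusted over the list alone, with the chaperone gene BIP1 1.66-fold lower (0.0540 without unstable mutant replicate 1). Of 6 core histone genes 2 fell (adjusted p = 0.0398, and adjusted p = 0.837 with an estimated correlation), and 5 adjusted over the list alone, with the centromeric histone gene CenH3 1.77-fold lower. Leaving out single arrays ended the calls of 3 of these lists and of the phenylpropanoid list. For histones the adjusted p was 0.106 without Nipponbare control replicate 1 and 0.105 without unstable mutant replicate 1, and for cell cycle genes 0.0916 without Nipponbare control replicate 2 and 0.0568 without unstable mutant replicate 2. For translation genes it was 0.162 without Nipponbare control replicate 1 and 0.0617 without unstable mutant replicate 2, and for phenylpropanoid genes 0.0866 without the same control array and 0.0524 without unstable mutant replicate 1.

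**Figure D3:**
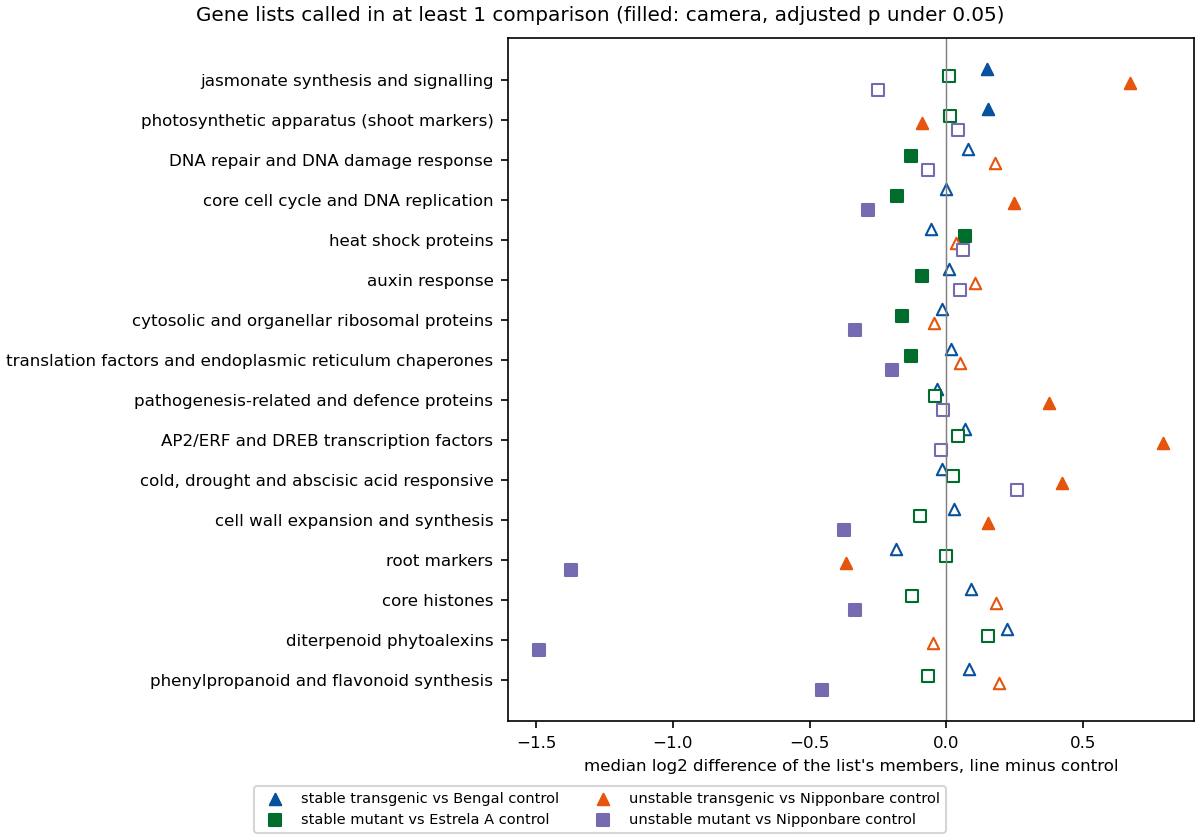
Median log2 difference of the members of each gene list (line minus its control) for the 4 lines, with filled symbols where camera at the preset correlation gave an adjusted p under 0.05. In the unstable mutant the diterpenoid list lies at -1.49 and the root markers at -1.38, and no call held with an estimated correlation.

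Over the whole array, 13085 probe sets (22.9%) were called in the unstable mutant, 7277 higher and 5808 lower, with 2957 changed at least 2-fold. The effect SD was 0.484. The count was 7862 from the 4 arrays alone, 8179 without unstable mutant replicate 1 and 1790 among probe sets not called between cultivars (an alternative added after the data had been seen). In the latter the balance turned, with 638 higher and 1152 lower.

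The unstable lines differed from each other at 16789 probe sets, 8979 higher and 7810 lower in the mutant, and 4698 by at least 2-fold. This balance turned with the scaling, with 47.3% higher after cyclic loess against 53.5%. CPDK2 (LOC4333181) was 23.4-fold higher in the mutant (11.03 ± 0.47 against 6.48 ± 0.51, adjusted p = 7.16e-06), BURP16 21.1-fold and the hemoglobin gene NSHB2 14-fold higher. For CPDK2 the Nipponbare, Bengal and Estrela A controls read 8.01, 10.59 and 10.12. The transgenic line thus lay below every control and the mutant above. COPT2 and APG8D were 11.6- and 10.9-fold higher. JAZ2 was lower in the mutant (3.31 against 10.69), DREB1G 32.6-fold, TPP1 28.7-fold, CYP701A8 28.6-fold and IRT1 26.3-fold lower. The folds of DREB1G and TPP1 were 16.5 and 14.8 without unstable transgenic replicate 1 and 64.2 and 55.9 without its replicate 2, and that of NSHB2 was 25.8 without unstable mutant replicate 1 and 7.62 without its replicate 2.

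Set against the unstable transgenic line, the unstable mutant had lower cell wall genes in 56 of 81 and higher ones in 5 (median -0.65, camera adjusted p = 1.3e-06, and adjusted p = 0.204 with an estimated correlation). Jasmonate genes were lower in 25 of 35 and higher in 2 (median -1.10, adjusted p = 3.65e-05, and adjusted p = 0.693 with an estimated correlation). Root markers were lower in 9 of 13 (median -1.15, adjusted p = 0.00206) and cell cycle genes lower in 29 of 49 and higher in 5 (adjusted p = 0.00263), and both calls were lost (adjusted p = 0.204 and 0.693 with an estimated correlation). Phenylpropanoid genes were lower in 22 of 32 and higher in 4 (adjusted p = 0.0104, and adjusted p = 0.204 with an estimated correlation). Diterpenoid genes were lower in 10 of 16 and histone genes in 6 of 6 (adjusted p = 0.0320 for both, and adjusted p = 0.693 with an estimated correlation). Ribosomal protein genes were lower in 15 of 26 and higher in 1 (adjusted p = 0.0353, and adjusted p = 0.734 with an estimated correlation). Adjusted over the list alone, the counts of lower genes were 58, 27, 10, 32, 22, 13, 6 and 15 in the same order.

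Against the same control, the mutant had 13085 calls and the transgenic line 4425, and the effect SDs were 0.484 and 0.310, with SDs between pairings of 0.0022 and 0.0026. Among probe sets not called between cultivars, an alternative added after the data had been seen, the counts were 1790 and 1522, with the filter resting on the same Nipponbare arrays as both comparisons. Of 223 probe sets that separate Nipponbare from both other controls, 30% stood at the other cultivars' level in the mutant (23.7% of those higher and 50% of those lower in Nipponbare) and 0% in the transgenic line. Each kind of modification was represented by 1 line here.

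Between the stable lines, the called counts of 94 (transgenic) and 75 (mutant) and the effect SDs of 0.104 and 0.134 lay closer together. Their pairings differed with SDs of 0.022 and 0.0050. The stable lines' effects differed at 122 probe sets, 45 higher and 77 lower in the mutant's effect, and 62 without stable mutant replicate 2 or 78 without Bengal control replicate 1. The unstable and the stable transgenic effects differed at 1116 probe sets (710 higher, 406 lower), between 324 without Bengal control replicate 2 and 2203 without unstable transgenic replicate 2. The unstable and the stable mutant effects differed at 5826 (3610 higher, 2216 lower), and at 2920 without Estrela A control replicate 1. The contrasted lines differ in cultivar too.

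**Figure D4:**
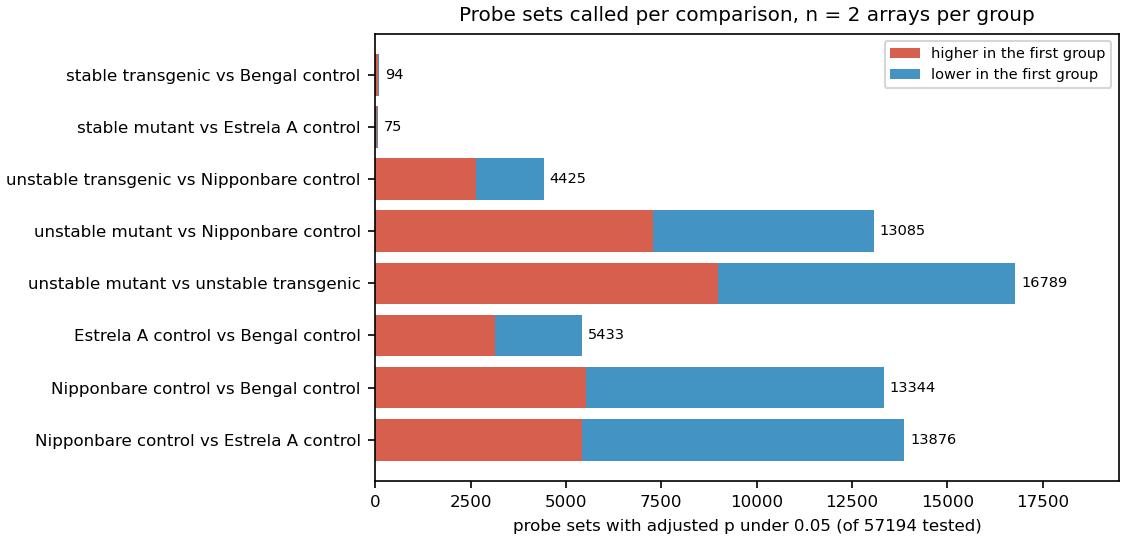
Number of the 57194 probe sets called (limma, adjusted p under 0.05) per comparison, split into those higher and lower in the first group named, with the total printed beside each bar. The line comparisons gave 94, 75, 4425 and 13085, and the control cultivars differed at 5433 to 13876.

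The control cultivars set the scale of these numbers. Any difference among the 3 was called at 16907 probe sets (29.6%), 5190 of them at least 2-fold. Estrela A and Bengal differed at 5433, Nipponbare and Bengal at 13344, and Nipponbare and Estrela A at 13876, with effect SDs of 0.513, 0.596 and 0.621. BURP17 (LOC4349896) was 398-fold higher in Nipponbare than in Bengal (13.18 ± 0.11 against 4.54 ± 0.24). JAZ2, EIL1, OsC3H40 and IRT1 were 152-, 47.5-, 46.5- and 45.1-fold higher. Estrela A read 14.11 for BURP17 and 10.2 for EIL1, so among the controls these genes were low in Bengal alone. For JAZ2, OsC3H40 and IRT1 Estrela A read 3.5, 4.045 and 5.53, near Bengal. RAB16B was 51.3-fold lower in Nipponbare, and AMY1.1, an alpha-amylase gene, 47.0-fold lower. BURP16 was 44.0-fold, ELA3 32.0-fold and LEA19 31.2-fold lower. AMY1.1 had an SD of 2.46 in Nipponbare and of 1.761 in Bengal. The Nipponbare SD was 1.202 for ELA3 and 1.287 for LEA19. The folds of AMY1.1, ELA3 and LEA19 were 14.1, 17.8 and 16.6 without Nipponbare control replicate 1 and 157, 57.7 and 58.7 without its replicate 2.

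Both transgenic lines, which have separate controls, shared 21 probe sets called in the same direction, against 4.05 for independent lists, and 4 in opposite directions, against 3.22. LOC9270995 rose by 1.57 in the stable and 2.15 in the unstable line on the log2 scale, and LOC4335593 fell in both, by 2.87 and 0.94. These genes were chosen after their values were seen. Stable transgenic and unstable mutant calls overlapped in the same direction at 16 (11.5 for independent lists) and in opposite directions at 24 (10.1). For the stable and unstable mutants these counts were 12 (8.62) and 20 (8.54), and the stable lines shared 0 in the same direction and 1 in opposite directions. The unstable lines shared 966 calls in the same direction, against 518 for independent lists, and 884 in opposite directions, against 495. In 20 simulations of unchanged groups on the same controls, 0 calls were shared. Unchanged groups are rarely called at all, so that count does not gauge the overlap. The changes of the unstable lines correlated across probe sets at 0.098, where unchanged groups on the same controls gave 0.50. These correlations are not alike in scale, since changes of a line's own lower them. The covariance of the lines' changes was 0.0186, against 0.0115 to 0.0125 in the simulations. With each line set against a different control array, a test added after the data had been seen, the correlation was -0.026 one way round and 0.0043 the other. The covariances were then -0.0054 and 0.00093. The calls shared in the same direction were then 311 (204 for independent lists) and 584 (444), and those in opposite directions 368 (198) and 675 (444). The excess in the same direction was thus no larger than that in opposite directions once no control array was shared.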

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

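Of the tests here, those of mixed pools, of root tissue, of chance placement and of alleles were chosen after the result was seen.

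All 3 interaction contrasts that were run are listed here, with no further selection. In each, the effects of 2 lines differed at some probe sets beyond the spread between pools. The stable mutant's effect differed from the stable transgenic line's at 122 probe sets, and at 62 without stable mutant replicate 2 or 78 without Bengal control replicate 1. The unstable transgenic effect differed from the stable transgenic one at 1116. That count was 446 without unstable transgenic replicate 1, 2203 without its replicate 2, 514 without Nipponbare control replicate 1, 648 and 443 without stable transgenic replicates 1 and 2, and 429 and 324 without Bengal control replicates 1 and 2. The unstable mutant's effect differed from the stable mutant's at 5826, with 3300 without unstable mutant replicate 1, 3608 and 3326 without stable mutant replicates 1 and 2, and 2920 without Estrela A control replicate 1. In each of these contrasts the lines also differ in cultivar.

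The unstable mutant stood almost as far from the Nipponbare control as other cultivars did. Of 223 probe sets that separate Nipponbare from both other controls by at least 3 log2 units, 30% stood at the other cultivars' level on both mutant arrays (23.7% of the 169 higher and 50% of the 54 lower in Nipponbare) and 57% at the Nipponbare level, against 0% and 84.8% in the unstable transgenic line. Cyclic loess left 12924 probe sets called and moved array medians by at most 0.09. The authors' normalization had already brought the arrays to a common distribution, so this cannot decide on a shift before or within that step. The linear share of Nipponbare signal was under 0.1 on both arrays for 25.4% of the 169 markers and above 0.5 for 61.5%. That spread argues against pools that only mix Nipponbare with Bengal or Estrela A seedlings, with expression otherwise unchanged. It cannot decide on mixing with a further cultivar, whose seedlings may hold the Nipponbare level at many markers. Seed of a further cultivar or a cross may account for the 30%, while the 57% argues against seed of Bengal or Estrela A as such, and the chromosome blocks that a cross would leave were neither shown nor excluded (61.3% of neighbouring pairs alike, central 95% of shuffles 45.2% to 63.4%). An effect of the irradiation stays open and untested, as does less root in the pools, since 76.9% of 13 root markers fell, which cannot be told apart from lower expression in the root.

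The genes called in the stable mutant lay close together on the chromosomes. Of 39 placed genes, 19 had another called gene within 20 array genes, where a permutation test with 10000 draws gave a mean of 3.17 and at most 13 (p = 0.0001, the smallest these draws can give). Chance placement is therefore argued against, and in the stable transgenic line 8 of 43 genes had such a neighbour (mean of draws 3.86, permutation p = 0.1). Segments that differ between the mutant and its control, by irradiation or by descent, may account for this, which was not tested. The draws place genes at random, so they cannot tell such segments from other reasons for neighbouring genes to be called together. Of 53 probe sets changed at least 2-fold, 24.5% (13) had the mutant at another cultivar's level and its control away from it and 31 had the reverse, with 5 counted in both and 14 in neither, which leaves it open whether alleles of other cultivars are involved.

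The transgenic lines shared calls in the same direction at 5.18 times the number for independent lists, against 1.4 times for the stable transgenic line and the unstable mutant. Hygromycin B, given to both transgenic lines alone, may contribute, and it cannot be told apart from transgenesis because every transgenic seedling received it. The share of stable transgenic calls found again was 22.3% in the unstable transgenic line and 17% in the unstable mutant, which grew without the antibiotic.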

How the results depend on the processing

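The alternatives restricted to probe sets not called between cultivars and with separate control arrays were chosen after the data were seen, and all others were planned. Every count below stays a count of both directions, and where it changed the cause was not tested unless fewer arrays, fewer probe sets or a fold threshold make it. Requiring a 2-fold change left 59 (stable transgenic), 1020 (unstable transgenic), 2957 (unstable mutant), 4698 (unstable lines against each other), 687 (unstable against stable transgenic effects), 2487 (unstable against stable mutant effects) and 5190 calls (cultivars), with overlaps of 8 and 2 (transgenic lines, same and opposite direction) and 157 and 86 (unstable lines). With separate control arrays the unstable lines shared 311 and 584 calls in the same and 368 and 675 in opposite directions, with fewer arrays behind each. Each comparison's own arrays gave 28 (stable transgenic), 35 (unstable transgenic), 7862 (unstable mutant) and 209 (transgenic effects). No moderation gave 24 (stable transgenic), 2318 (unstable transgenic), 42 (stable effects) and 199 (transgenic effects), and a trended robust prior 152 for the stable transgenic line. Probe sets not called between cultivars gave 1522 (unstable transgenic, 1123 higher and 399 lower) and 1790 (unstable mutant, 638 and 1152), where filter and comparisons share the Nipponbare arrays. At or above the median signal, effect SDs were 0.161 (stable mutant), 0.377 (unstable transgenic) and 0.630 (unstable mutant), so dim probe sets dilute them, and the last was 0.470 without shared probe sets. All 24 gene list calls of the 4 lines (9 up, 15 down) were lost with an estimated correlation, leaving 0 of 116 by camera (7 at an unadjusted p under 0.05), while fry, which does not set a list against other genes, called 25. Leaving out 1 array at a time gave 51 to 65 (stable transgenic), 47 to 62 (stable mutant), 1349 to 5613 (unstable transgenic), 8179 to 13209 (unstable mutant), 12738 to 14209 (unstable lines), 62 to 108 (stable effects), 324 to 2203 (transgenic effects), 2920 to 7436 (mutant effects), 13090 to 16958 (cultivars) and 22 to 27 list calls. The jasmonate list of the stable transgenic line turned direction without stable transgenic replicate 1, with adjusted p between 1.54e-06 and 0.968 over these fits. The replicate numbers do not pair the arrays, since deviations of same-numbered arrays correlated between groups from -0.208 to 0.115 (median -0.019, 2 of 21 above 0.1). With them as a replicate block the counts were 84 (stable transgenic), 73 (stable mutant), 3935 (unstable transgenic), 12559 (unstable mutant) and 16359 (unstable lines). Of the calls of single genes and probe sets looked at, 9 of 25 (stable transgenic), 17 of 23 (stable mutant), 2 of 81 (unstable transgenic), 88 of 112 (unstable mutant) and 10 of 10 (unstable lines) held in all settings with every array. Over genes and lists named, 2342 values kept direction and side of the threshold, 471 lost the call and 1 turned.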

Other observations

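Only planned tests are reported below, and the 1 gene known by an identifier alone was picked after its values were seen.

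Of 8 clock genes 1 rose and 4 fell in the unstable mutant, and the list was not called by camera (adjusted p = 0.25). LHY (LOC4344703), a morning-phased clock gene, rose 4.98-fold (12.37 ± 0.09 against 10.05 ± 0.01, n = 2), while PCL1 was 4.39-fold, OsPRR1 2.59-fold and GI 1.45-fold lower. The hour of sampling is not given in the sources used here. Clock genes were not called in the other lines (0 of 8 in each, limma). Grain remnant markers rose in 4 of 15 in the unstable mutant, with the alpha-amylase genes AMY3E and AMY3D 3.61- and 2.21-fold higher (list adjusted p = 0.613). These lost their calls without unstable mutant replicate 2 (AMY3E, adjusted p = 0.297, 2.15-fold, against 6.04-fold without replicate 1) and Nipponbare control replicate 2 (AMY3D, 0.173). Photosynthesis genes rose in 7 of 29 and fell in 5 (list adjusted p = 0.817), with GLK1 2.08-fold and PSAG 2.62-fold higher and LFNR1 2.03-fold lower. GLK1 read 11.78 in the mutant, near Estrela A (11.69), while PSAG, at 11.21, stood above Bengal (10.32) and Estrela A (10.7). Of 7 low-oxygen genes 3 rose, NSHB2 by 4.71-fold (adjusted p = 0.141 and 2.56-fold without unstable mutant replicate 2, 8.66-fold without replicate 1), and 2 fell, with Adh2 2.68-fold lower (list adjusted p = 0.935). NSHB2, at 10.69 in the mutant, lay below Bengal (11.34) and Estrela A (11.62), as did Adh2 (10.45, against 11.19 and 10.99). Of 30 dwarf genes 11 rose and 7 fell (list adjusted p = 0.262), with the gibberellin synthesis gene KAO 4.20-fold higher and CPS1 2.72-fold lower. KAO, at 8.96, stood above Bengal (8.55) and Estrela A (7.88). CPS1 read 5.265, near Estrela A (5.165) and below Bengal (6.71).

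Further groups split in the unstable mutant, with the p-values of camera for the whole list. DNA repair genes rose in 4 and fell in 7 of 29 (adjusted p = 0.670), with the replication protein A gene OsRPA32 2.62-fold lower and the photolyase gene LOC9272017 1.56-fold higher. Of 37 chromatin and silencing genes 3 rose and 5 fell (adjusted p = 0.846), with the DNA methyltransferase genes CMT3 and MET1 2.11- and 2.02-fold lower. Heat shock genes rose in 9 and fell in 8 of 51 (adjusted p = 0.629), jasmonate genes rose in 3 and fell in 9 of 35 (adjusted p = 0.240), and defence genes rose in 7 and fell in 3 of 25 (adjusted p = 0.789). The vacuolar iron transporter gene VIT1.2 was 4.11-fold higher. It read 12.52 in the mutant, near Bengal (12.67) and Estrela A (12.92), while the Nipponbare control read 10.47. In the unstable transgenic line, LOC4331398 rose by 7.47 on the log2 scale, from a low level of 4.09 ± 0.13 to 11.55 ± 0.09 (SE 0.12, adjusted p = 2.4e-11), and lay between 3.88 and 4.30 on the other 12 arrays.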
